A study of Mus musculus with 16 samples.

How the data were processed

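RNA of mouse spinal cord was measured on 16 single-colour arrays, and the deposited table holds 1 intensity for each of 12488 probe sets on each array. The control probe sets carry the prefix AFFX, as on Affymetrix arrays. The software that made the values is not given in the sources used here. The authors' intensity values are linear, and their mean after trimming 2% of probe sets at each end lay between 800.4 and 800.5 on every array, so the deposited intensities were taken as already scaled by the authors and were not normalized again. The median intensity per array was 289 to 383.6. The number of arrays limits the precision of every value.

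Intensities below the 20th percentile of all values, 60.9 or 5.93 on the log2 scale, were set to it, and log2 was taken; differences of genes near this floor are understated. The 66 control probe sets were left out of every test. Genes were named from GEO's platform annotation, in which 10833 of the remaining probe sets have 1 symbol, 396 have several and 1193 have none. Of those with 1 symbol, 10817 were matched by Entrez ID to the RefSeq gene table of GRCm38.p6, used for names only, and 0 symbols changed. A probe set was tested where its mean log2 value over all arrays was above the 40th percentile of such means. For a gene with several probe sets, the one with the highest mean was tested. This left 6427 probe sets, 5694 with a symbol and 733 without a single symbol; the latter were tested and not named.

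Groups, titled sex, age and letter were read from the titles. Ctr was read as control and Spa as spastic; sev is given as titled, the letter M in Spa-M was not interpreted, and 3+ months was used as a lower bound of 3. The 16 arrays were averaged over titles that differ only in the letter a or b, which gave 10 samples, 6 of them of 2 arrays: 4 control, 5 spastic and 1 B6C3Fe. The consensus correlation of arrays that share a title was 0.23. The groups, comparisons, tests, gene lists, the rule for naming genes and most alternatives were fixed before the data were examined.

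Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend), with group and titled sex in the model, all groups sharing 1 estimate of the spread, and Benjamini-Hochberg adjustment over all genes tested; tests were 2-sided, and a gene was called at an adjusted p under 0.05. The contrasts were spastic minus control, spastic minus B6C3Fe, B6C3Fe minus control, 12 minus 9 months among controls, female minus male, sev minus other spastic samples and sev minus the sample titled M. A group of 1 sample was assumed to vary like the others. Genes beyond both references were those called in both spastic contrasts in the same direction, and since the contrasts share the spastic arrays the overlap was set beside simulated unchanged groups. Positive differences mean higher in the group named before minus.

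The 26 gene lists covered glycinergic, GABAergic and glutamatergic transmission, motor neurons, interneurons, neurons, astrocytes, microglia, oligodendrocytes, immature oligodendrocytes, cholesterol synthesis, immediate early genes, chaperones and stress, cell death and injury, interferon and MHC, ion channels, oxidative phosphorylation, ribosome, Hox genes, skeletal muscle, blood, Schwann cells, sensory neurons, meninges and matrix, endothelial and mural cells, and sex. Lists with 3 or more genes tested were compared with the other genes by limma's camera, 2-sided, with a preset correlation of 0.01, and again with an estimated correlation; fry, which asks whether a list moves one way on balance, was an alternative. Members called were counted over all genes tested and adjusted over the list alone. RNA quality was tested with exact permutation tests on the ratios of 3-prime to 5-prime control probe sets.

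Named genes were, for each comparison, up to 10 called genes with the largest difference in each direction or, where 0 were called, the 5 smallest p-values in each direction; up to 4 called members of each list; 14 genes of glycine and GABA transmission and glia fixed in advance for both spastic contrasts; the sex list in female minus male; and the 15 largest genes beyond both references.

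The alternatives were other floors (10th and 40th percentile), no filter or a 60th percentile filter, quantile normalization, every array as its own replicate or with the sample as a random block or the letter as a replicate block, only the 1a arrays, every probe set tested, eBayes without a trend, no sex term, B6C3Fe among the controls with and without log2 of age, no B6C3Fe arrays, control samples only, and leaving out each sample in turn. Chosen after seeing the data were fits without the 2 spastic samples titled male, with only samples titled female, without array a of the 9-month female controls, and with the Pcx ratio as a covariate. The fits were tested on simulated data with 200 of 6427 genes changed. For spastic minus control, 88.5% of 2-fold and 99.5% of 4-fold changes were recovered. The shares were 47% and 93% for spastic minus B6C3Fe, and 37% and 93.5% for B6C3Fe minus control. In the simulation every sample had the same spread for a gene, independent between genes and without a floor. Lone samples thus varied like the others by construction. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Scanner files were not used here.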

Results

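The series holds 16 single-colour arrays of mouse spinal cord RNA, each with 12488 probe sets. The titles put 8 arrays in a control group of 9 and 12 months, 6 in a spastic group of 2 to 6 months, and 2 in a group named B6C3Fe, a hybrid mouse stock, of 1 month. Spastic mice carry a recessive mutation of Glrb, the gene for the beta subunit of the inhibitory glycine receptor, and have muscle rigidity and tremor. By title, 8 arrays are from females and 8 from males. Arrays whose titles differ only in the letter a or b were averaged, which left 4 control, 5 spastic and 1 B6C3Fe samples. The labels do not say whether such arrays are separate animals, and p-values measure only the spread between samples. The median intensity per array ran from 289 to 383.6, and 14.7% to 24.1% of values lay at or under the floor of 60.9. The number of arrays limits the precision. The titled ages of the spastic mice lie between that of the B6C3Fe mice and those of the controls, except that the age titled 3+ months is only a lower bound, so group and age change together.

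Glrb separated the spastic arrays from all others. It had a log2 intensity of 13.00 ± 0.12 (SD, n = 4) in controls, 10.57 ± 0.47 (SD, n = 5) in spastic cords and 12.95 in the B6C3Fe sample. Single arrays ran from 12.70 to 13.30 in controls, from 9.92 to 11.11 in spastic cords and from 12.92 to 12.98 in B6C3Fe. Which part of the transcript the probe set reads is not given in the sources used here. The titled sex matched the values on 14 of 16 arrays. Xist, the RNA that silences an X chromosome in females, lay between 10.55 and 12.07 on the 8 arrays titled female and between 5.93 and 5.97 on the 6 control and B6C3Fe arrays titled male. On the 2 spastic arrays titled male it was 10.37 and 10.54. Eif2s3y, a Y-linked gene, was at 8.50 to 9.09 on the control and B6C3Fe arrays titled male and at the floor of 5.93 on the spastic arrays titled male. Uty and Kdm5d, also Y-linked, were at the floor on both of these spastic arrays. By these values all 6 spastic arrays have the female pattern, while the control arrays hold both. Spastic and control samples thus differ in sex pattern too. The fits use the sexes as titled.

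**Figure D1:**
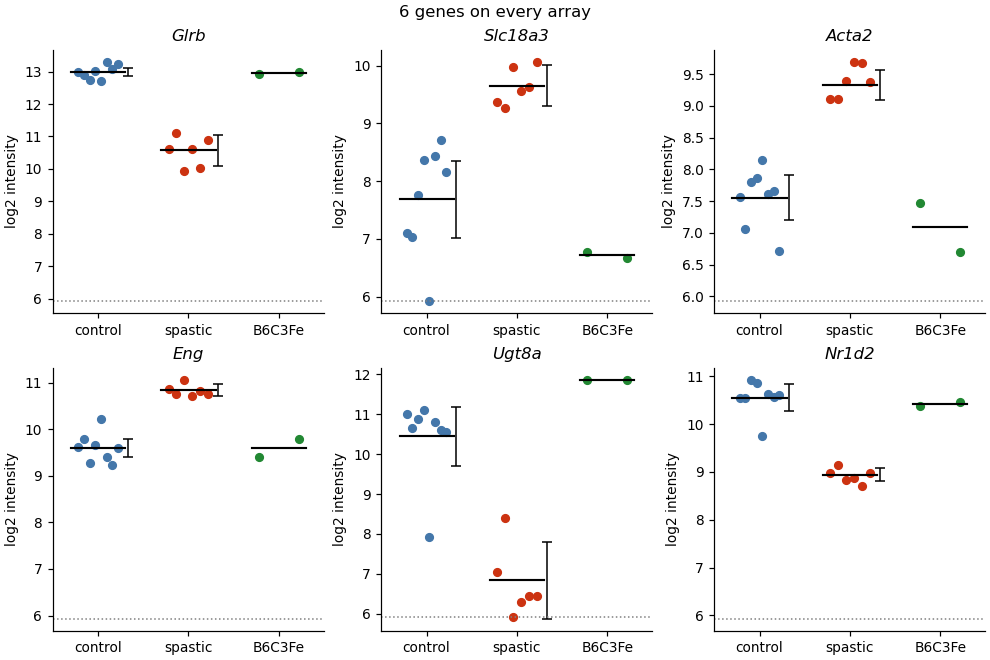
Log2 intensity of 6 genes (vertical axes) on each array, by group (horizontal axes); each point is an array, black lines are means of samples, bars are the SD between samples and the dotted line is the floor. Glrb is lower on every spastic array (9.92 to 11.11) than on any control array (12.70 to 13.30), and Slc18a3 is higher on every spastic array (9.26 to 10.07) than on any control array (5.93 to 8.71).

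Spastic against control cords asks what differs in the mutant spinal cord. Glrb was 5.41-fold lower in spastic cords (log2 difference -2.44, SE 0.21, adjusted p = 0.000311). Slc18a3, the vesicular acetylcholine transporter of motor neurons, was 4.15-fold higher (2.05, SE 0.17, adjusted p = 0.000311). Ugt8a, which makes the galactolipids of myelin, fell by 3.64 on the log2 scale (SE 0.47, adjusted p = 0.00157), and Myh4, a fast skeletal muscle myosin, fell by 3.44 (SE 0.44, adjusted p = 0.00142). Further large falls were those of the kinesin Kif5c (-2.87), the dendritic protein Map2 (-2.85), the synaptic calcium sensor Syt1 (-2.83) and the fucosyltransferase Fut9 (-2.57). Car3 (-2.33), Eny2 (-2.31) and the SNARE protein Vamp7 (-2.31) were also lower. The largest rises after Slc18a3 were Ppp2r5d (1.82), the smooth muscle actin Acta2 (1.78), Tns2 (1.72), the endothelial clotting factor Vwf (1.67), St6galnac6 (1.63), Tspan4 (1.58), Actb (1.55), the cell cycle inhibitor Cdkn1a (1.53) and Erdr1 (1.52). All of these passed limma's test. Cdkn1a lost its call in 2 of the fits that left out 1 sample, with no filter and without sex in the model. Actb lost it with B6C3Fe among the controls and log2 of age in the model, and Map2 with only the 1a arrays.

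Parts of these falls lie near the floor or rest on 1 probe set. Kif5c and Car3 were at the floor on 4 of 6 spastic arrays, Myh4 on 3, Map2 on 2, and Ugt8a, Syt1, Fut9, Vamp7 and Eny2 on 1, which makes the spastic values too high; 1 control array was also at the floor for Kif5c and Map2. Further probe sets of Myh4 (0.17) and Vamp7 (0.05) did not show the fall. Array a of the 9-month female controls was lower than array b for Kif5c (-3.57), Map2 (-3.63), Syt1 (-3.49), Ugt8a (-2.89), Eny2 (-2.26) and Slc18a3 (-2.50).

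In all, 1270 of 6427 genes (19.8%) differed, 632 higher and 638 lower, and 2203 had an unadjusted p under 0.05. The count was 723 without the 12-month female controls, 810 without the 12-month male controls and 790 without the 9-month male controls. It was 396 without the 2 spastic samples titled male and 165 with only samples titled female, both with fewer samples. With the B6C3Fe sample among the controls 1053 genes were called, and with log2 of age in that model 701, 570 of them among the 1270; with the 3-prime to 5-prime ratio of the Pcx control probe sets as a covariate, an alternative chosen after seeing the data, 9 were called. Over the 1270 genes the median size was then 0.47 in place of 0.58, and 1269 kept their sign.

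Among the genes of inhibitory transmission, Glrb and GABA-A receptor subunits were lower, and a vesicular transporter and a GABA-B receptor subunit higher. In the glycinergic list 1 of 7 genes was lower, Glrb, and 1 was higher, Slc32a1, the vesicular transporter of GABA and glycine (0.65, SE 0.14, adjusted p = 0.0106). Slc32a1 lost its call with only the 1a arrays, and with B6C3Fe among the controls and log2 of age in the model. The ligand-binding subunit Glra1 showed no detectable difference (0.02, SE 0.31, adjusted p = 0.967), nor did the scaffold gephyrin, Gphn (0.11, adjusted p = 0.536), or the glycine transporter Slc6a9 (0.23, adjusted p = 0.226). Glra2, Glra3, Slc6a5 and Chat have 0 probe sets here, and Gad2 lay below the filter (mean log2 7.45). In the GABAergic list 4 of 8 genes were lower and 1 higher. The GABA-A receptor subunits Gabra2 (-2.11, adjusted p = 0.00296), Gabrg1 (-1.60, adjusted p = 0.00157) and Gabrb1 (-0.96, adjusted p = 0.0059) fell, and the GABA-B receptor subunit Gabbr1 rose (0.65, adjusted p = 0.00229). Array a of the 9-month female controls was also below array b for Gabra2 (-1.99) and Gabrg1 (-1.17). Gabrb1 lost its call with B6C3Fe among the controls, with and without log2 of age. Its log2 intensity was 9.96 in the B6C3Fe sample, below the spastic mean of 10.31. Gad1, which makes GABA, was at -0.25 (adjusted p = 0.133). Neither list passed camera as a whole (adjusted p = 0.884 and 0.157). Fry gave adjusted p = 0.56 for the glycinergic and 0.0335 for the GABAergic list.

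Excitatory and neuronal genes went both ways. Of 11 glutamatergic genes 3 were lower, the AMPA receptor subunits Gria2 (-0.95, SE 0.11, adjusted p = 0.000719) and Gria3 (-1.55, adjusted p = 0.0208) and the metabotropic receptor Grm8 (-0.70, adjusted p = 0.0249). Glul, glutamine synthetase, was 2.83-fold higher (adjusted p = 0.00809), but its other probe set was at a log2 difference of 0.03. Of 7 motor neuron genes 3 were higher, Slc18a3, acetylcholinesterase Ache (0.80, adjusted p = 0.00417) and the neurofilament Nefm (0.39, adjusted p = 0.0482), and 1 was lower, the neurofilament Nefl (-1.10, SE 0.16, adjusted p = 0.00216). Of 13 interneuron genes 2 rose, somatostatin, Sst (0.65, adjusted p = 0.0056), and calretinin, Calb2 (0.32, adjusted p = 0.0473), and 2 fell, calbindin, Calb1 (-0.46, adjusted p = 0.0239), and Tac1 (-0.53, adjusted p = 0.0489). Of 22 general neuronal genes 4 were higher, among them Sncb (0.83), and 4 lower, among them Map2 and Syt1. Camera gave adjusted p = 0.927 for the glutamatergic, 0.487 for the motor neuron, 0.563 for the interneuron and 0.8 for the neuronal list. Fry gave adjusted p = 0.0464 for the motor neuron list and 0.24 or more for the others. With log2 of age in the model, the calls of Gria3, Calb1, Calb2, Tac1 and Sncb were lost. The calls of Gria3, Grm8, Nefm, Calb1, Calb2 and Tac1 were lost in at least 1 of the fits that left out a sample, those of Nefm in 7 and of Calb2 and Tac1 in 8 of them.

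Genes of blood vessels rose together in spastic cords. Of 13 endothelial and mural cell genes 10 were higher and 0 lower by limma, with a median log2 difference of 0.86, and camera put the list apart from other genes (adjusted p = 4.19e-07, and adjusted p = 0.0229 with an estimated correlation). Acta2 rose 3.44-fold (SE 0.21 on the log2 scale, adjusted p = 0.000787). The TGF-beta coreceptor endoglin, Eng, rose 2.36-fold (1.24, SE 0.12, adjusted p = 0.00036), the glucose transporter of the blood-brain barrier, Slc2a1, 2.51-fold (1.33, adjusted p = 0.0018), and the efflux pump Abcb1a 2.39-fold (1.26, adjusted p = 0.00162). The tight junction gene Cldn5 (1.04), the cadherin Cdh5 (0.86), Tagln (0.71), the VEGF receptor Flt1 (0.71) and Bsg (0.50) were also higher; these 5 are further members of the list, named after their values were seen. Pecam1 (0.72, adjusted p = 0.252), Itm2a (-0.13) and Rgs5 (-0.27) did not pass the test. Vwf was called from 1 probe set, while its other probe set showed 0 difference at the floor. Adjusted over the list alone, 10 genes were called. With the Pcx ratio as a covariate, Eng was the only one of these genes still called. Array a of the 9-month female controls was above array b for Eng (0.815), Acta2 (0.529) and Vwf (0.451), and below it for Abcb1a (-0.241) and Slc2a1 (-0.087).

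**Figure D2:**
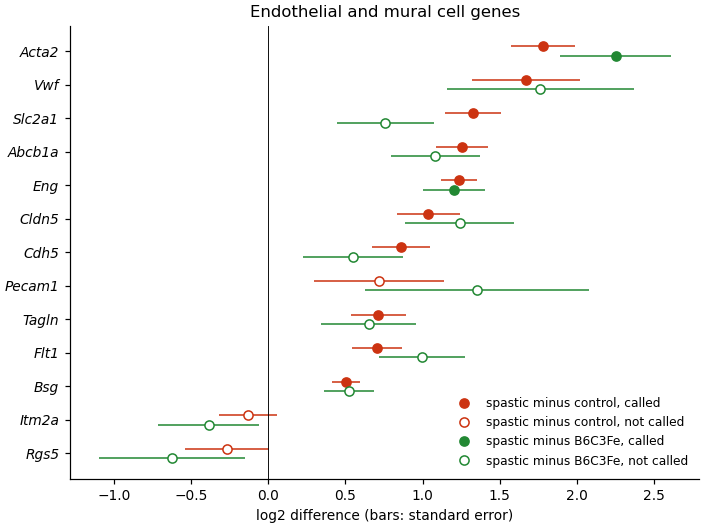
Log2 difference (horizontal axis) of each of 13 endothelial and mural cell genes (vertical axis), spastic minus control in red and spastic minus B6C3Fe in green; bars are standard errors and filled points are genes called by limma. Against control, 10 genes are called higher and 0 lower, and against B6C3Fe 2 are called, Eng and Acta2.

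The astrocyte and microglial markers that differed were all lower. Of 13 astrocyte genes 2 fell, the water channel Aqp4 (-0.82, SE 0.16, adjusted p = 0.00593) and S100b (-0.64, adjusted p = 0.00595), while Gfap, raised in reactive astrocytes, was at 0.16 (adjusted p = 0.621). Of 19 microglial genes 4 fell, Mpeg1 (-0.87, adjusted p = 0.0118, with its other probe set at the floor), Lgmn (-0.48, adjusted p = 0.013), Ctss (-0.58, adjusted p = 0.026) and Tyrobp (-0.68, adjusted p = 0.0463), and the phagocyte marker Cd68 was at 0.20 (adjusted p = 0.408). Of 13 oligodendrocyte genes 3 fell, Ugt8a, Car2 (-0.53, adjusted p = 0.0175) and Apod (-0.35, adjusted p = 0.0442), and 1 rose, Sox10 (0.43, adjusted p = 0.025), while myelin basic protein, Mbp, was at 0.05 (adjusted p = 0.906). Apod turned to 0.12 with log2 of age in the model (adjusted p = 0.549). Of 19 genes of immature oligodendrocytes 2 rose, Sox4 (0.46, with its other probe set at -0.14) and Tmsb10 (0.45). With 1 sample left out, the call was lost in 8 fits for Apod, 7 for Tyrobp, 5 for Sox10, 4 for Sox4, 3 for Car2, 2 for Ctss and 1 for Tmsb10. With log2 of age in the model, Tyrobp, Ctss, Sox10, Sox4 and Tmsb10 lost their call as well as Apod. Camera gave adjusted p = 0.113 for the astrocyte and the microglial list, 0.563 for the oligodendrocyte and 0.487 for the immature list.

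Members of the remaining lists went both ways. Of 17 cholesterol synthesis genes 4 were lower, among them Sc5d (-0.79, adjusted p = 0.00674) and Msmo1 (-0.43, adjusted p = 0.0415), and 1 was higher. Of 18 immediate early genes 3 rose, Ier3 (0.66, adjusted p = 0.00471), Btg2 (0.72, adjusted p = 0.0266) and Ier2 (0.63, adjusted p = 0.0463). Of 21 chaperone and stress genes Hspb8 rose (0.55, adjusted p = 0.00695), and Hspa8 (-0.47) and Xbp1 (-0.46) fell. Of 14 cell death and injury genes Cdkn1a and Tnfrsf1a (0.53) rose, and cytochrome c, Cycs, fell (-0.88, adjusted p = 0.0027). Of 14 interferon and MHC genes Ifit3 (-0.93) and B2m (-0.81) fell, and of 14 ion channel genes the potassium channel genes Kcnab1 (-0.73), Kcnd2 (-0.80) and Kcna2 (-1.20). Of 29 oxidative phosphorylation genes 3 rose, among them Ndufb7 (0.51, with its other probe set at the floor) and Atp5j (0.38), and 2 fell, Cox6c (-0.42) and Sdha (-0.36). Of 14 ribosomal genes Rps18 rose (0.42), and of 19 Hox genes Hoxb5 (0.41) and Hoxd10 (0.94) rose. Of 18 meningeal and matrix genes 5 rose, among them the basement membrane collagens Col4a1 (0.94, adjusted p = 0.0056) and Col4a2 (0.53, adjusted p = 0.012) and fibronectin, Fn1 (0.59, adjusted p = 0.0163), and decorin, Dcn, fell (-0.75, adjusted p = 0.0146). Of 15 skeletal muscle genes Myh4 and Actn3 (-0.80) fell, of 4 blood genes 0 were called by limma, with 0 also when adjusted over the list alone, of 2 Schwann cell genes Ncam1 rose (0.49), of 2 sensory neuron genes Tac1 fell, and of the sex genes only Xist was tested and not called. With 1 sample left out, the call was lost in 8 fits for Hoxd10, Ier2 and Tac1, in 7 for Hoxb5, Tnfrsf1a and Msmo1, in 6 for B2m and Sdha, in 5 for Rps18 and Atp5j, in 4 for Kcna2, in 3 for Btg2 and Xbp1, in 2 for Hspa8, Cdkn1a and Cox6c, and in 1 for Ifit3, Dcn, Actn3 and Ncam1. With B6C3Fe among the controls and log2 of age in the model, the calls of Col4a1, Col4a2, Fn1 and Dcn were lost. So were those of Kcnab1, Kcnd2, Kcna2, Ifit3, B2m, Btg2, Ier2, Tnfrsf1a, Hspa8 and Xbp1. Cox6c, Sdha, Ndufb7, Atp5j, Rps18, Hoxb5, Hoxd10 and Tac1 also lost their call in that fit. Camera called none of these remaining lists, with the smallest adjusted p = 0.104 for the immediate early and the meningeal list, and 3 of the 26 lists had under 3 genes tested.

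Adjusted over the list alone, the counts matched those over all genes for most lists. They were 3 higher and 3 lower for the glutamatergic list, 3 and 2 for interneurons, 5 and 5 for neurons, 0 and 6 for microglia, 2 and 3 for oligodendrocytes, 2 and 0 for immediate early genes, 5 and 3 for oxidative phosphorylation, 0 and 0 for Hox genes, 6 and 1 for meninges, and 1 and 0 for the sex list. The median and the mean differed in sign in the glycinergic, glutamatergic, neuronal, cholesterol, ribosomal and Hox lists. Of the 88 genes that the naming rule took and that were called, 54 kept their call with each sample left out in turn, 53 with log2 of age in the model, 40 without the 2 spastic samples titled male and 5 with the Pcx ratio.

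Spastic against B6C3Fe sets the spastic cords beside younger mice. Xist was at 10.37 or above on every spastic array and at the floor on both B6C3Fe arrays, and Eif2s3y was the reverse. The sex pattern thus changes with the group here, and the fit corrects only for the sex as titled. The differences below hold that correction and can exceed those of the measured means. Slc18a3 had a mean of 9.66 in spastic samples and was at 6.72 in the B6C3Fe sample, a smaller gap than the fitted 3.44. Slc18a3 was 10.9-fold higher in spastic cords (3.44, SE 0.29, adjusted p = 0.000617) and Glrb 5.48-fold lower (-2.45, SE 0.35, adjusted p = 0.013). Ugt8a fell by 5.19 on the log2 scale (SE 0.82, adjusted p = 0.0164) and Fut9 by 3.21. Haemoglobin alpha, Hba-a1, was 8.36-fold higher (3.06, SE 0.59, adjusted p = 0.0314). Other large rises were St6galnac6 (2.70), Crip1 (2.60), Tns2 (2.42), the calcium sensor Ncs1 (2.36), the adenylyl cyclase Adcy4 (2.27), Acta2 (2.25) and Acsf3 (2.11); Stx3 was called higher too, at 7.51 to 8.38 in spastic samples and at the floor on both B6C3Fe arrays. Other large falls were the endothelin receptor Ednrb (-2.29), Ccdc88a (-2.03), the myelin protein Mog (-1.67), the cell cycle inhibitor Cdkn1c (-1.51), the clock gene Nr1d2 (-1.39), gelsolin, Gsn (-1.38), and the helicase Dhx36 (-1.37). Of the glycine and GABA genes, Glra1 (0.46, adjusted p = 0.66), Gphn (0.28, adjusted p = 0.459), Slc6a9 (-0.65, adjusted p = 0.145), Slc32a1 (0.25, adjusted p = 0.591) and Gad1 (0.41, adjusted p = 0.261) were not called. Gfap (-0.52), Cd68 (-0.12) and Mbp (-0.23) were not called either.

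Camera called 3 lists against B6C3Fe, and the oligodendrocyte and cholesterol lists, which lay lower, lost their call with an estimated correlation. Fry called 4 lists, the oligodendrocyte, cholesterol, endothelial and motor neuron lists. Of 13 oligodendrocyte genes 5 fell, the myelin genes Mog, Mal (-1.35, SE 0.18, adjusted p = 0.013) and Cldn11 (-0.79, adjusted p = 0.035) with Gsn and Ugt8a (camera adjusted p = 0.000177, and adjusted p = 0.177 with an estimated correlation). All 17 cholesterol synthesis genes had negative differences, with a median of -0.87, but only Msmo1 was called (-1.12, adjusted p = 0.0351); the list had camera adjusted p = 1.13e-07, and adjusted p = 0.386 with an estimated correlation. The endothelial list was higher (adjusted p = 1e-05, and adjusted p = 0.0459 with an estimated correlation), with Eng (1.20) and Acta2 called. Adjusted over the list alone, 7 oligodendrocyte genes were lower and 1 higher, 10 cholesterol genes lower and 7 endothelial genes higher. Camera did not call the other 20 lists tested. The median of the cholesterol list was 0.037 in spastic minus control and 0.767 in B6C3Fe minus control. That of the oligodendrocyte list was -0.241 and 0.445. In all 132 genes differed, 91 higher and 41 lower, with 1304 at an unadjusted p under 0.05, and with no filter on dim probe sets 85 were higher and 94 lower. The B6C3Fe group is 1 sample, with the lowest 3-prime to 5-prime ratio of beta actin (-2.25), assumed to vary like the others, and the count was 66 without the 12-month female controls, 35 without the 9-month male controls, 70 without the spastic sample titled Spa1, 32 without that titled 3+ months, 10 without that titled sev and 6 without both of the spastic samples titled male. Of the 30 genes that the naming rule took and that were called, 4 (Slc18a3, Glrb, Mal and Crip1) kept their call with each sample left out in turn, 3 without both of the spastic samples titled male, 5 with only the 1a arrays and 4 with the Pcx ratio.

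A change that ran one way with age would put spastic cords between the references, by the titled ages; whether genes run one way over these ages was not tested. Genes were sought that differed from both references in the same direction. Against B6C3Fe the sex pattern of Xist and Eif2s3y changes with the group as well, and no fit used the sex that these values show. There were 64, of which 43 were higher and 21 lower in spastic cords, and 1 further gene was called in opposite directions. The most changed, by the smaller of both sizes, were Ugt8a, Fut9, Glrb, Ednrb (-2.25 against control), Slc18a3, Ccdc88a (-2.15), Acta2, Tns2, St6galnac6, Nr1d2 (-1.60, SE 0.14, adjusted p = 0.000356), the receptor phosphatase Ptprd (-1.47), Eng, Dhx36 (-1.09), the nuclear envelope protein Sun2 (0.96) and Acsf3 (0.87), whose 2 other probe sets did not rise against control. Array a of the 9-month female controls differed from array b for St6galnac6 (-2.96), Tns2 (1.76), Ccdc88a (-1.72) and Fut9 (-1.36). It also differed for Nr1d2 (-0.879), Eng (0.815) and Acta2 (0.529), the way of the spastic difference, and for Acsf3 (-0.809) the other way. Groups simulated without change shared 0.01 genes on average and at most 1 in 100 simulations. They held no difference in either contrast, so they could share hardly any genes and say little about the 64. Independent lists of these sizes would share 8.95 higher and 4.07 lower genes. With the spastic samples split between the contrasts, 2 to 49 genes were shared, with a median of 10.5 over 10 splits. The split contrasts share no spastic samples but also have fewer of them, so the cause of the fall from 64 cannot be told. The count was 33 without the 12-month female controls, 110 without the 9-month female controls, 17 without the 9-month male controls, 34 without the spastic sample titled Spa1, 18 without that titled 3+ months, 7 without that titled sev and 4 without both of the spastic samples titled male.

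**Figure D3:**
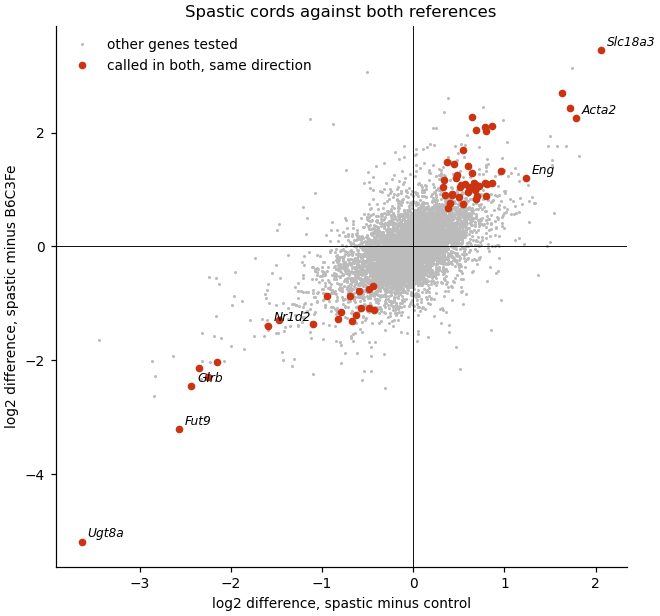
Log2 difference of each of 6427 genes, spastic minus control (horizontal axis) against spastic minus B6C3Fe (vertical axis); red points are the 64 genes called in both contrasts in the same direction. Glrb lies at -2.44 and -2.45, Slc18a3 at 2.05 and 3.44.

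B6C3Fe against control compares mice of 1 month with mice of 9 and 12 months, which also differ in the name of their group. Elastin, Eln, was 3.76-fold higher in B6C3Fe cords (1.91, SE 0.24, adjusted p = 0.00864), though not by its other probe set (-0.05), and the oligodendrocyte list genes Mal (1.65, SE 0.18, adjusted p = 0.00567), Gsn (1.78, adjusted p = 0.0323) and Cldn11 (0.93, adjusted p = 0.0389) were higher too, with the kinase Fyn (1.06, adjusted p = 0.044). Hba-a1 was 11.9-fold lower (-3.58, SE 0.59, adjusted p = 0.0389). Stx3 was also lower, at the floor on both B6C3Fe arrays and at 8.83 ± 0.09 (SD, n = 4) in controls. Crip1 (-2.22), the synaptotagmin Syt4 (-1.78), Snrk (-1.60), Rangap1 (-1.36), Cryz (-1.34), the splicing factor Srsf5 (-1.31) and the proteasome genes Psmd12 (-1.29) and Pomp (-1.23) were also lower. Cholesterol synthesis genes were higher as a list, 16 of 17 with positive differences and 0 called by limma (camera adjusted p = 1.68e-07, and adjusted p = 0.401 with an estimated correlation). So were the oligodendrocyte list, with 3 genes called (adjusted p = 0.00229), and the immature oligodendrocyte list, with 0 called (adjusted p = 0.0192), each with adjusted p = 0.297 with an estimated correlation. Adjusted over the list alone, 10 cholesterol genes, 5 oligodendrocyte genes and 3 immature oligodendrocyte genes were higher, and 1 oligodendrocyte gene lower. In all 25 genes differed, 5 higher and 20 lower, with 965 at an unadjusted p under 0.05. With no filter on dim probe sets the balance turned, with 53 higher and 25 lower. The count was 4 without the 9-month male controls, and 12 or fewer without any other control sample or any spastic sample except that titled 3+ months. Of the 15 named genes, Eln, Mal and Snrk kept their call in every alternative fit tried.

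Between controls of 12 and 9 months, limma called 0 genes, with 346 at an unadjusted p under 0.05. The smallest p-values belonged to the heat shock gene Hspa1b (-2.94, SE 0.51, adjusted p = 0.569) and Fancc (-1.39, adjusted p = 0.569), followed by Lsr (-1.32), Sgk1 (-1.89) and Cryab (-0.74) on the lower side. On the higher side were Otog (1.27), Cryl1 (0.95), Nrcam (0.76), Adam23 (0.60) and the transferrin receptor Tfrc (0.57). In simulated data, 58.5% of 2-fold and 95% of 4-fold changes were recovered in this comparison.

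Between the sexes as titled, limma called 0 genes, with 389 at an unadjusted p under 0.05. Xist was at 2.75 (SE 0.79, adjusted p = 0.798). The smallest p-values were those of Fgfr3 (-1.24, adjusted p = 0.262), Slc48a1 (-0.74, adjusted p = 0.262), Slc18a3 (-0.85), Muc1 (-1.30), Nde1 (-0.44), Lum (1.19), Gm8096 (1.12), Col15a1 (0.73), Mtpn (0.68) and Septin2 (0.48). In control samples alone 2 genes were called, Xist (5.52, SE 0.33, adjusted p = 9.27e-05) and a probe set without a single symbol (-5.02, adjusted p = 9.27e-05). Without the 2 spastic samples titled male, these and Urm1 (-1.83, adjusted p = 0.00805) were called; the last was chosen after its values were seen.

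The spastic array titled sev was set against the 3 other spastic samples without the letter M, and limma called 0 genes, with 239 at an unadjusted p under 0.05 and a smallest adjusted p = 0.0813. The named genes with the smallest p-values were Scoc (1.17, SE 0.18, adjusted p = 0.152), Chmp6 (1.66), C1d (1.23), Dnajb9 (1.15) and Myadm (0.82) on the higher side. On the lower side were the class I gene H2-K2 (-2.16, adjusted p = 0.63), the noncoding RNA Gas5 (-3.27), Trim59 (-1.62), Nkx2-2 (-1.23) and Fgfr2 (-0.92). Skeletal muscle genes were higher as a list, 13 of 15 with positive differences and 0 called, and 0 adjusted over the list alone (camera adjusted p = 9.08e-05, and adjusted p = 0.753 with an estimated correlation). The other 22 lists tested were not called. Muscle genes varied between spastic arrays. Acta1 was at 11.75 on the sev array, at 10.61 and 12.65 on those titled Spa1 and Spa2, and at 8.30 on that titled 3+ months. Myh4 was at 6.32, 8.58, 6.84 and 5.93 in the same order. The sev array was thus the highest for neither gene. All spastic arrays have the female pattern, but the fits correct for the sex as titled, so fitted and measured differences can differ. Gas5 was at 9.72 on the sev array and at most 12.67 in other spastic samples, a smaller gap than the fitted -3.27. Cox6a2 was at 9.85 on the sev array and at 6.65 in the sample titled M. That gap is smaller than the 4.48 fitted below. For Gnas, at 13.17 and 15.27 in the same order, the fitted -2.08 was close to the measured gap. Against the 6-month spastic sample titled M, which differs in age and titled sex as well, limma called 0 genes, with 358 at an unadjusted p under 0.05. The smallest p-values were those of growth hormone, Gh (-4.22, SE 0.59, adjusted p = 0.23), Pkm (-1.85), Gnas (-2.08), Tuba1c (-3.22) and Tuba1a (-1.83), and of Snhg11 (1.14), Reln (1.27), Cox6a2 (4.48), Kcnk1 (1.45) and Cntrl (2.00). The sev group is 1 array, and 20.5% of 2-fold and 92% of 4-fold changes were recovered in simulated data for the comparison with the other spastic samples. Leaving out the spastic sample titled 3+ months gave 4 calls, and that titled Spa1 1 call, against the other spastic samples; against the sample titled M, leaving out the 12-month male controls gave 29, the 9-month male controls 1 and the sample titled 3+ months 2.

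RNA quality was compared between 5 spastic and 4 control samples with 2-sided exact permutation tests over 126 splits. The log2 ratio of the 3-prime to the 5-prime control probe sets was -0.31 ± 0.21 (SD) in spastic and -0.25 ± 0.38 in control samples for Gapdh (exact p = 0.77), and -0.06 ± 0.43 and 0.26 ± 0.42 for beta actin (exact p = 0.302). The log2 median intensity was 8.28 ± 0.09 in spastic and 8.45 ± 0.08 in control samples (exact p = 0.0397, 0.0992 after Benjamini-Hochberg adjustment over 5 measures). Both remaining control genes were added after seeing the data: Pcx at 2.38 ± 0.38 and 1.73 ± 0.22 (exact p = 0.0238, adjusted 0.0992) and Tfrc at 0.97 ± 0.68 and 1.48 ± 0.20 (exact p = 0.222, adjusted 0.37). The B6C3Fe sample had a beta actin ratio of -2.25, with its arrays at -3.29 and -1.21, below every spastic and control array. Array a of the 9-month female controls had a Gapdh ratio of 0.995, where array b had -0.46. Across the 1140 genes called without these controls, array a minus array b correlated with spastic minus control at r = 0.434, and across all genes tested at r = 0.234; genes are not independent replicates.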

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

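The tests on sex-linked genes, RNA quality, pituitary genes, the sex splits and the age adjustment of Glrb were chosen after the result was seen. Of 310 groups of samples examined for the named genes, 27 had a sample far from the others by Dixon's ratio. This ratio is a sample's gap to the nearest sample over the group's range. Of the 27 groups, 8 were in control and 19 in spastic samples. Chance gives about 5%. Some named genes, such as Gh and Gas5, were chosen for small p-values in the comparisons of the sev sample. They were thus picked because a spastic sample differed, so the 27 cannot be weighed against that 5%.

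The count of genes that differed between spastic and control cords, 1270, was weighed against chance, age and RNA quality. Of 100 splits of the 9 samples into 4 and 5, 1 called as many genes, the real split itself, and the highest other called 440. That other split put 1 spastic sample with the 4 controls, so it was close to the real one. A share under 1 in 100 could not be seen with these splits, so chance is argued against but not excluded. Nor can such splits set aside age, which changes with the group. For the endothelial list 1 of 100 splits gave a camera p as small as 1.82e-08, the real one, and the lowest other gave 5.58e-07. With the B6C3Fe sample among the controls 1053 genes were called, and with log2 of age in that model 701, 55.2% of 1270 as a count, with 570 in common; that percentage ran from 0.236% to 72.4% over fits that left out 1 sample (0.236% without the B6C3Fe sample), so for the genes as a whole age and mutation cannot be told apart. Glrb kept -2.52 with log2 of age (SE 0.22, adjusted p = 0.000412; -3.08 to -2.27 with 1 sample left out), and in each of these fits its value plus 2 SE lay below 1 in 2 of the unadjusted difference, which argues against age as its whole cause. RNA quality stays open as a candidate explanation for part of the count: array a minus array b of the 9-month female controls correlated with spastic minus control across 1140 called genes at 0.434 (0.234 across all genes tested), 59.4% of these genes moved the same way, and with the Pcx ratio, which ran from 1.53 to 2.02 in control and from 2.00 to 2.98 in spastic samples, 9 genes were called, the median size falling from 0.58 to 0.47 while the median SE rose from 0.13 to 0.20 and 1269 of 1270 genes kept their sign (Glrb was then at -1.78, SE 0.19, adjusted p = 0.0181).

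The 2 spastic arrays titled male carried a female pattern. The female minus male difference of Xist in spastic samples minus that in control samples was -5.09 (adjusted p = 0.00162 in limma's interaction test, which called 3 genes, with 449 at an unadjusted p under 0.05). A mix of female and male RNA is argued against by Eif2s3y, which was at the floor of 5.93 on both arrays where male arrays had at least 8.50. Sexes mislabelled in the titles are a candidate explanation, since Xist was at 10.37 or above on both arrays; no biological explanation was tested. Of 100 splits of the samples by sex, 100 called as many genes as the titled sexes, which called 0, and the highest other called 26; no split can call fewer than 0, so this decides nothing about that count.

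The 6-month spastic arrays titled M had the pituitary hormones Gh at 13.20 and 13.26 and Prl at 13.00 and 13.06, where the 14 other arrays reached at most 10.91 and 9.65. On both arrays, 0.0311% of genes tested lay above all other arrays by 2 log2 units. All arrays share a trimmed mean of 800.4 to 800.5, which leaves little room for a large share, so this does not decide on array scale. By any size, 4.15% of genes tested (267 of 6427) lay above all other arrays on both. Pituitary tissue in the sample stays open. Of 20 other pituitary genes with a probe set, 2 lay above all other arrays by any size, where 4.15% of all genes tested did so. They were Pomc (9.15 and 9.41 against at most 8.77) and Cga (9.13 and 9.37 against at most 9.06). Of the list, 15 genes passed the filter and 2 are in another list. The count of 2 above all other arrays lies between what pituitary RNA and its absence were held to give. That rule was set after the values were seen, and it counts genes that were dim here. Gnrhr was at the floor on 16 arrays, Tshb on 12 and Avp on 10. The count therefore cannot tell pituitary RNA from its absence. Gh and Prl were the only 2 of 6427 genes above all other arrays by 2 log2 units. Age and the meaning of M were not tested as biological explanations.

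In the same sample the Dixon ratio was 0.877 for Gh, 0.931 for Gnas, 0.831 for Pkm, 0.769 for Tuba1a, 0.796 for Tuba1c, 0.737 for Glra1, 0.721 for Xist, 0.791 for Cox6c and 0.87 for Dhx36, each of them higher than in the other spastic samples. The sample titled sev was lowest for Gas5 (0.787), Nkx2-2 (0.812), Crip1 (0.752) and Cd68 (0.725) and highest for Kcnd2 (0.715). The spastic sample titled Spa2 was highest for Car3 (0.972) and lowest for Hoxb5 (0.814) and Rangap1 (0.733), that titled 3+ months was lowest for Sc5d (0.86), and that titled Spa1 was lowest for St6galnac6 (0.758). For Car3 the other spastic samples lay at 5.93 to 5.99, at or near the floor. Among controls, the 9-month females were lowest for Kif5c (0.963), Map2 (0.836) and Aqp4 (0.86) and highest for Tac1 (0.925). The 12-month males were lowest for Actb (0.94), Reln (0.938) and Hspa8 (0.848), and the 12-month females for Mpeg1 (0.869).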

How the results depend on the processing

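The fits without the 2 spastic samples titled male, with only samples titled female, without array a and with the Pcx ratio were chosen after the result was seen. Where a count fell with fewer samples or arrays, the construction itself gives less power; for other changes the cause was not tested. Against main counts of 1270, 132, 25 and 64 for spastic minus control, spastic minus B6C3Fe, B6C3Fe minus control and beyond both references, leaving out each sample in turn gave 723 to 1273, 10 to 197, 4 to 26 and 7 to 110. The 1a arrays alone gave 759, 9, 8 and 4. Every array as its own replicate gave 1895, 626, 520 and 316, and the sample as a random block 1500, 323, 231 and 164. With the letter as a replicate block the counts were 1818, 515, 525 and 278; the labels do not say that a letter joins arrays of different titles, and array a minus array b correlated across genes between such titles at -0.04 to 0.16, with 1 of 15 pairs over 0.1. Leaving out the 2 spastic samples titled male gave 396, 6, 9 and 4, and only samples titled female 165 for spastic minus control. With the Pcx ratio 9, 11 and 2 genes were called in the spastic contrasts and beyond both, and with the B6C3Fe sample among the controls and log2 of age 701 in spastic minus control (1053 without the age term), 570 of them among the 1270. Without a trend, 49, 4 and 27 were called in spastic minus B6C3Fe, B6C3Fe minus control and beyond both. Without array a of the 9-month female controls, 206 and 121 were called in spastic minus B6C3Fe and beyond both. B6C3Fe minus control gave 78 with no filter, 43 with quantile normalization and 43 without sex.

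For the counts of 0, every array as its own replicate gave 10 for 12 minus 9 months, 3 for female minus male and 4 for sev minus M; the random block gave 2 for 12 minus 9 months and 1 for sev minus M. Control samples alone gave 2 and leaving out the 2 spastic samples titled male 3 for female minus male. Sev minus other spastic gave 1 with no filter and 3 without sex, and 0 to 4 with 1 sample left out; sev minus M gave 1 with no filter, 1 without sex and 0 to 29. Of the lists, spastic minus control called 1, and 3 by fry, 3 with log2 of age, 2 with quantile normalization, 2 without the spastic samples titled male, 2 with only samples titled female, 2 with the Pcx ratio and 1 to 3 with 1 sample left out. Spastic minus B6C3Fe called 3, then 1 with an estimated correlation and 4 by fry. B6C3Fe minus control called 3, then 0 with an estimated correlation, 0 by fry and 5 without the spastic samples titled male. Sev minus other spastic called 1, then 0 with an estimated correlation, 0 by fry and 1 to 3 with 1 sample left out.

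Apod, called lower in spastic minus control, turned to 0.12 with log2 of age. Of the uncalled genes, Glra1 in spastic minus control turned to -0.001 with quantile normalization, -0.139 without array a, -0.067 with the Pcx ratio and -0.326 to 0.249 with 1 sample left out. Log2 of age turned Gad1 to 0.058, Gfap to -0.128 and Slc6a9 to -0.172. Mbp in spastic minus control turned to -0.001 with B6C3Fe among the controls, -0.063 without array a, -0.035 with the Pcx ratio and -0.195 to 0.212 with 1 sample left out. Cd68 against B6C3Fe turned to 0.003 without sex, 0.038 with the letter as a replicate block, 0.071 without the spastic samples titled male and -0.19 to 0.034 with 1 sample left out. For genes named and called in spastic minus control, planned fits kept 1155 calls, lost 129 and reversed 1, leave-one-out fits kept 729 and lost 151, and added fits kept 155 and lost 197. Signal over background limits what can be said of genes near the floor, where 14.7% to 24.1% of values lie.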

Other observations

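The list of clock genes and the other groups in this part were chosen after the result was seen, and no explanation is offered for them. Nr1d2, a nuclear receptor of the circadian clock, was lower in spastic cords than in both references, and other clock genes moved in several directions against control. Clock (-0.84, adjusted p = 0.00382) and the nuclear receptor Rora (-1.18, adjusted p = 0.00287) fell and Per1 rose (0.68, adjusted p = 0.015). Nr1d1 (0.09, adjusted p = 0.69), Arntl (-0.12, adjusted p = 0.628), Dbp (0.42, adjusted p = 0.128), Per3 (-0.40, adjusted p = 0.161) and Cry1 (0.48, adjusted p = 0.203) were not called by limma. Against B6C3Fe, Nr1d2 was the only called gene of the 13 clock genes tested.

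Among the 64 genes beyond both references were several outside the rule for naming, picked here for their known roles after their values were seen. The motor protein dynein heavy chain Dync1h1 was higher (0.86 against control, 1.12 against B6C3Fe), as were Vapb (0.69 and 0.84) and the superoxide dismutase Sod1 (0.53 and 1.07), and the spectrin Sptan1 (0.40 and 0.76). The chemokine receptor of venules, Ackr1, was also higher (0.80 and 2.03), and Txnip, a regulator of glucose uptake, likewise (0.68 and 0.99). The isocitrate dehydrogenase Idh1 was lower (-0.57 and -1.09).

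The 6-month spastic arrays titled M held Glra1 at 11.35 to 11.51, where the other spastic arrays lay at 10.06 to 10.42, and Gnas at 15.25 to 15.29, where the other arrays lay at 13.03 to 14.52. Glrb on these arrays was at 10.03 to 10.61, within the range of the other spastic arrays, 9.92 to 11.11. The muscle actin Acta1 was at 8.55 to 8.90 on them, at 8.30 to 12.65 on the other spastic arrays and at 11.20 to 12.44 on control arrays.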
